A study of Drosophila melanogaster with 17 samples.

How the data were processed

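Ovaries of 2 to 4 day old Drosophila melanogaster females were profiled in 17 libraries in 6 groups. RNA-seq and RNA polymerase II (Pol2) ChIP-seq were each made from 3 wild-type and 3 cuff mutant samples. ChIP of Cutoff (Cuff) was made in 2 samples beside 3 input controls, which carry no immunoprecipitation. Per the labels' protocols, each biological replicate was a separate dissection of about 30 females, total RNA was depleted of ribosomal RNA before strand-tagging library preparation, and the Cuff ChIP used GFP antibodies against an EGFP fusion of Cuff.

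The tools named per the submitters' processing notes are cutadapt 1.2.1, Bowtie2 2.0.0, TopHat2 2.0.8, SAMtools 0.0.19, bedtools, MACS2 2.0.10.20130501 and DESeq 1.16.0, with genome build dm3. Apart from DESeq for the gene tables and a mention of MACS2 in the peak names, which tool made which file is not given in the sources used here. Neither is the annotation, or whether counting used strand or whole gene bodies. Each of the 2 gene tables is, per the file headers, DESeq output with pooled dispersion estimates taken from the parametric fit alone. It lists protein-coding genes with 1 value per genotype, so the libraries of a genotype are merged. The deposited genotype values are a signal that is never below 0, printed to 1 decimal, and are called the authors' means below. They are taken to be read counts divided by size factors and averaged, which the headers do not state. The authors' log2 fold change is printed to 1 decimal, mutant over wild type. The authors' p-value is printed to 1 significant digit, and the headers do not say whether it was adjusted for multiple tests. Of the p-values for RNA 69.3% were 0.5 or more, and of those for Pol2 80%. In Pol2 202 genes had p of 0.05 or less, where unadjusted p-values of unchanged genes would give 689.9, so the Pol2 values at least look adjusted already. In RNA 1155 genes did, where 625.2 would be given, so this count does not show adjustment there. Where p was already adjusted, any further adjustment here, over all genes or over a list, would be a second one and too strict. A p-value listed at 0 (40 RNA genes, 8 Pol2 genes) is below the smallest other value printed, 3e-14 for RNA and 2e-13 for Pol2. The Cuff peaks are 1 deposited list of positions with the authors' score per peak. The peak names in it mention MACS2, a reproducibility step and all 3 control numbers; which statistic the score is was not stated. The score is used only to rank and filter peaks within this list.

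No per-library values were analysed here, so depth per library, spread between replicates and SDs are not given. Planned count tests, limma on replicates, the replicate block, leaving out libraries, the interaction between assays and an estimated inter-gene correlation therefore could not be run. A gene was counted as changed where the authors' deposited p was 0.05 or less, and as higher or lower by the authors' means. The authors' own calls also required a 2-fold difference. Fold changes are ratios of the authors' means. Medians over gene lists use log2 of the value plus 1, which understates changes of genes with low values. No fold is given against a genotype listed at 0. Other gene symbols were matched through a gene table of assembly Release 6. It gave a current symbol and a gene length for 12366 of 12505 RNA genes and 13648 of 13797 Pol2 genes, and its positions serve only for gene length and for the order of genes along each arm.

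For each of 21 gene lists the members past the threshold were counted over all genes and adjusted over the list alone (Benjamini-Hochberg on the deposited p). Each list's median was placed among the medians of 10000 random lists, each member being replaced by 1 of the 200 genes nearest in level. Lists with at least 5 measured members outside the central 95% of random medians are called apart. This describes the merged values, since genes are not replicates. The planned camera test needs replicate values; its preranked form was run first, and the percentile was made the leading result only after its output and the level trend in Pol2 had been seen. A match on level and gene length together was also chosen after seeing the data. The preranked form and Fisher's exact test, which call fewer RNA lists, are given as alternatives. With permuted real changes, 40 simulated lists of 30 genes shifted by a log2 of 0.5 were apart in 87.5% of cases at RNA values (12505 genes) and in 100% at Pol2 values (13797 genes); unshifted lists of that size were apart in 2.5% and 5%. For lists of 10 genes the share was 55% at RNA values and 100% at Pol2 values, so small RNA lists can be missed, and unshifted lists of 70 genes were apart in 10% of cases at Pol2 values. The permutation removed the trend with gene length and any correlation between list members. The shares for unshifted lists therefore need not hold for the real lists. Overlap of calls between assays was compared with the product of both counts over the genes in both tables, with Fisher's exact test, two-sided. Peaks were counted in windows around 5 known piRNA clusters by an overlap of 1 bp, with approximate dm3 positions. Cuff peaks were not assigned to genes, since no dm3 gene annotation was used here.

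Gene lists, the first set of alternatives and the rule for named genes were fixed before the data were examined. The rule takes, per assay, the 10 largest changes in each direction with p under 0.05 and a value in the higher genotype above the median of all genes, up to 3 members per list with the smallest p, the genes cuff, rhi, del, jing and Pld, up to 5 genes changed in both assays in the same and in opposite directions, and the 10 highest-scoring peaks. Genes named outside it were chosen after their values were seen, and are said to be so. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1. Alternatives covered the 2-fold requirement, low-value filters, the pseudocount, a repeated adjustment of p, centring on level, other list tests, and the peak threshold, overlap and window size.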

Results

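The study compared wild-type ovaries with ovaries mutant for cutoff (cuff), which encodes a partner of Rhino and Deadlock in the transcription of piRNA clusters. RNA levels and polymerase II occupancy were measured with 3 libraries per genotype, and binding of Cuff itself with 2 ChIP and 3 input libraries. The RNA table held 12505 protein-coding genes, with the authors' means summing to 89336038 in wild type and 85598452 in the mutant. The Pol2 table held 13797 genes, summing to 51692649 and 50036639. The Cuff ChIP came as 1 list of 937 peaks. The replicate values behind the genotype means were not analysed here, so values below carry no SD of their own. Spread between libraries enters only through the deposited p. Its dispersion was taken from the parametric fit alone, so disagreement between the libraries of a single gene need not show in its p.

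The first question was which transcripts change when Cuff is mutant. The cuff transcript itself had authors' means of 951 in wild type and 1105 in the mutant, with p = 0.9 in the authors' deposited table. The labels do not name the allele, so this value neither checks nor contradicts the genotype. By the deposited p, 688 genes were higher and 467 lower in the mutant, 1155 of 12505. Of these the authors called 526 higher and 313 lower with at least a 2-fold difference.

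Several transcripts close to absent in wild type were abundant in the mutant. CG4415, now named gNacalpha, had the largest rise, from an authors' mean of 61.8 to 67559, or 1093-fold. CG42854 rose 393-fold (18 to 7079.1), CG5111 350-fold (16.1 to 5637.1) and CG43290 144-fold (33.4 to 4810.9). CG8964 (otk2), related to the receptor off-track, rose 98-fold (103.5 to 10137). CG15599, CG7442, skpC, CG4842 and CG9095 rose between 30.5-fold and 58.1-fold. All of these 10 are listed at p = 0 in the authors' deposited table.

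Among the transcripts that fell, CG42704 went from an authors' mean of 1817.7 to 1.7. Iris, a host gene derived from a retroviral envelope, fell 18.4-fold (1906.7 to 103.7). mRpL27, a protein of the mitochondrial ribosome, fell from 17887 to 1752.3. CG34355 was 12.3-fold lower, CG9509 11.8-fold lower and the glutathione transferase gene GstE11 10.8-fold lower. CG12716, Mco1, CG13822 and CG15418 were between 5.79-fold and 8.95-fold lower.

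Most genes of the piRNA pathway did not pass the threshold in RNA. Of 38 measured members 1 rose, 2 fell and 35 did not pass, with 1 adjusted over the list alone, and the list median of -0.07 lay at percentile 39.4 of level-matched random lists. The methylosome gene vls fell 3.11-fold (2997 to 964.6). AGO3, a slicer of the ping-pong cycle, fell 1.82-fold (66595 to 36574), and qin, its regulator, rose 1.84-fold (5968.5 to 10973). For rhi (2920.9 and 3594.5) and del (11606 and 13882), the partners of Cuff, p was 0.7 and 0.9 in the authors' deposited table. Of the genes that flank the 42AB piRNA cluster, jing rose 3.85-fold (3715.2 to 14303; p = 2e-05 in the authors' deposited table), whereas Pld had authors' means of 4358.6 and 6882.1 with p = 0.3 there.

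Members of the follicle cell and muscle lists that passed all rose. In the follicle cell list 10 of 26 members rose, 0 fell and 16 did not pass, 6 adjusted over the list alone. They include the ecdysone-response genes Eip75B (3111.4 to 11457, 3.68-fold) and br (1544.3 to 5092.6, 3.3-fold), and peb (2.92-fold), a zinc finger factor of follicle cells. In the muscle list 9 of 28 rose, 0 fell and 19 did not pass, 6 adjusted over the list alone, with the giant sarcomere genes bt at 4.15-fold and sls at 4.49-fold, and the myosin heavy chain Mhc at 3.45-fold (2309.7 to 7971.3). Both medians, 0.86 and 0.71 on the log2 scale, lay at percentile 100 of level-matched lists. Members of both lists are long genes. Matched on level and gene length, the follicle list lay at percentile 98.8 and the muscle list at 96.3, inside the central 95%.

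Members of the hemocyte, fat body, neuron and immune lists that passed also rose. The hemocyte list, 3 of 14 higher and 3 adjusted over the list alone, had a median of 1.10 at percentile 99.4 and 98.5 by both matches. Its members Pxn, Cg25C (Col4a1) and vkg make or modify the extracellular matrix and rose 4.93-fold, 2.56-fold and 2.11-fold. In the fat body list 2 of 15 rose (2 adjusted over the list alone), the storage protein gene Lsp2 3.24-fold and the lipid droplet gene Lsd-1 2.77-fold. In the neuron list 2 of 19 rose (2 adjusted over the list alone), Appl 4.87-fold and Syx1A 2.17-fold. In the immune list 4 of 46 rose (1 adjusted over the list alone), among them the antibacterial peptide genes AttA (3.9-fold) and AttB (2.3-fold) and the thioester protein gene Tep2 (4.45-fold). The fat body, neuron and immune lists lay at percentiles 89.7, 92.4 and 70.7, and with length matched at 90.8, 61.4 and 67.7. Of their members 13.3%, 10.5% and 8.7% passed, against 9.23%, 9.23% and 9.24% of other genes. The counts of passing members alone therefore do not set these lists apart. With a pseudocount of 10 the neuron list lay at 98.4, outside the central 95%.

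Genes of the gut lay lower, and in the spermatheca list 1 gene fell. The gut list had a median of -0.58 at percentile 0.675, 1.26 with length matched, and 3.2 with changes centred on level, inside the central 95%. The maltase gene Mal-A1 went from an authors' mean of 329.6 to 1.6, and Mal-A7 from 47.2 to a value listed at 0, the 2 of 26 members that fell, 1 adjusted over the list alone. Only 2 of the 26 had a wild-type mean of 50 or more. Send1, a protease of the spermatheca, was the 1 of 6 members of its list that fell (1 adjusted over the list alone), from 798.9 to 0.3. That list's median of 0.26 and mean of -1.10 differ in sign, at percentile 70.9.

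Eggshell and yolk genes divided. Of 24 chorion and vitelline membrane genes 7 fell and 2 rose, 4 adjusted over the list alone. The chorion genes Cp15 (629696 to 300466, 2.1-fold) and Cp18 (2.27-fold) fell, as did yellow-g2 (2.47-fold), which acts in the vitelline membrane. The list lay at percentile 0.14, and 11.8 with length matched. The yolk protein genes Yp1 and Yp2 rose 1.92-fold and 2.01-fold, 2 of 3 and 2 adjusted over the list alone, while Yp3 had authors' means of 63450 and 47065.

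Genes that lie in heterochromatin fell more often than they rose. Of 26 members 6 fell and 2 rose, 5 adjusted over the list alone, with a median of -0.39 at percentile 0.22, and 0 with length matched. The vacuolar sorting gene lt fell 2.62-fold (28256 to 10804). CG41056 (Pzl) and CG42621 (Myo81F) rose 6.62-fold and 4.97-fold. Ribosomal protein genes had a median of -0.28 at percentile 0.08, 2 of 85 rising and 6 falling (4 adjusted over the list alone). Among these, RpS5a fell 2.44-fold, RpS10a rose 5.3-fold (909.7 to 4821.1), and RpL22-like rose from 3.3 to 129.8, a change from near the floor. Of the mitochondrial ribosomal proteins 6 of 73 fell and 0 rose (1 adjusted over the list alone), mRpS33 by 2.56-fold and mRpL34 by 2.26-fold, at percentile 0.02. With length matched these lists of short genes lay at percentiles 34.2 and 82.7.

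Other lists held changes in both directions. In the female germline list 3 of 45 rose and 4 fell (5 adjusted over the list alone), including the differentiation factor bam (3.06-fold lower), pip (2.68-fold higher) and the synaptonemal complex gene c(3)G (2-fold higher). DNA damage and apoptosis genes, 3 higher and 3 lower of 34 (1 adjusted over the list alone), included the recombination gene spn-B (2.75-fold lower), Ku80 (2.12-fold lower) and Xrp1 (2.27-fold higher). Of 22 heat shock genes 2 rose and 3 fell (4 adjusted over the list alone). Hsp22 was 3.15-fold lower and Hsp26 2.26-fold lower. Hsp67Bb, 3.14-fold lower, had nearly the values of Hsp22, so these 2 are read as 1 measurement. Detoxification genes, 1 higher and 3 lower of 39 (2 adjusted over the list alone), lay at percentile 1.19, at 11 with length matched, at 10.5 with a pseudocount of 10 and at 2.82 with a mean of at least 50, the last 3 inside the central 95%. Cyp6a17 fell 30.3-fold (754 to 24.9), the glutathione transferase GstD1 2.86-fold and Ugt35b 11.4-fold. These germline, DNA damage and heat shock lists lay at percentiles 81.9, 60.3 and 94.4, and with length matched at 63.4, 63.4 and 99.4, the last outside the central 95%.

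No member of the testis list passed in RNA, over the 40 of 70 that were measured or adjusted over the list alone. Their median of 0.56 lay at percentile 98, but inside the central 95% with length matched (93), a pseudocount of 0.1 (94.2), a mean of at least 1 (95) or 50 (97.1), or centring on level (91.9). Only 15 had a wild-type mean of 50 or more. The smallest p there belonged to Pif1A (1069 and 2368.1), mia (312.5 and 656.5) and bol (1305 and 2154.1). In the termination and RNA decay list the exonuclease gene pcm rose 1.74-fold, 1 of 33 and 0 adjusted over the list alone, at percentile 92.1, and at 99.2 with length matched, outside the central 95%. Among 7 histone genes the embryonic linker histone CG3509 (BigH1) fell 1.7-fold, with 0 adjusted over the list alone, at percentile 29.9.

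Not every gene or list named above held in other tests. With the deposited p adjusted again, the RNA changes of AGO3, qin, Yp1, Yp2, Cp18, vkg, Lsd-1, Syx1A, Tep2, AttB, Mal-A7, RpL22-like, mRpS33, mRpL34, c(3)G, Ku80, Xrp1, Ugt35b, pcm, CG3509 and Mur18B no longer passed. The preranked camera test called the follicle, muscle, gut, neuron and mitochondrial ribosomal lists in RNA. It did not call the hemocyte, heterochromatin, eggshell, testis, detoxification or ribosomal protein lists, with adjusted p across genes of 0.057, 0.31, 0.31, 0.057, 0.057 and 0.16.

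The direction of RNA change went with gene length. Genes higher in the mutant had a median length of 11.1 kb, those lower 1.51 kb, and the rest 2.33 kb. With genes split by length into 5 classes, 413 of 2473 in the longest class were higher and 44 lower, against 50 of 2474 higher and 173 lower in the shortest. Across genes with a mean of 50 or more, Spearman's rho between length and log2 change was 0.46, and across all 12366 genes with a length it was 0.25; genes are not independent replicates. Split by signal per kb into 10 classes, the median log2 change was -0.05 in the lowest class, 0.82 in the next and -0.24 in the highest.

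**Figure D1:**
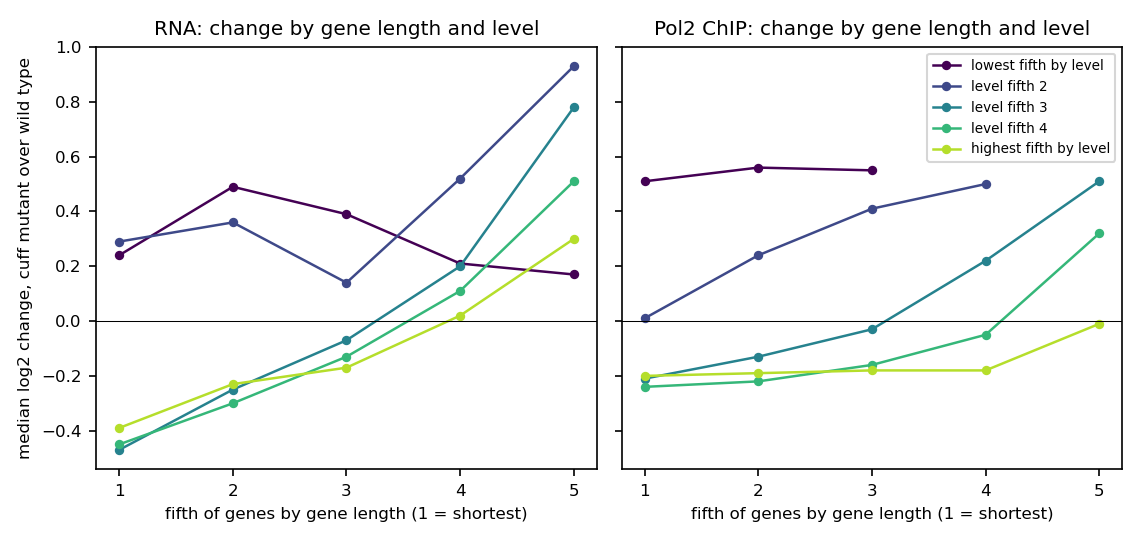
Median log2 change of genes in 5 classes by gene length (horizontal axis) and 5 by level (lines), for RNA and Pol2 ChIP; classes with fewer than 50 genes are left out. In RNA the class with the highest level runs from -0.39 for the shortest to 0.30 for the longest genes, and in Pol2 ChIP the class with the lowest level starts at 0.51. The middle Pol2 class by level runs from -0.21 for the shortest to 0.51 for the longest genes.

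The second question was where polymerase occupancy of genes changes in the mutant. By the deposited p, 112 genes had more Pol2 signal and 90 less, 202 of 13797. Of these the authors called 56 and 28 with at least a 2-fold difference. Eggshell genes were the listed group with the most losses. Cyp6a17 had the largest fall, 70-fold from an authors' mean of 2112.6 to 30.2. That mutant value lies below 165.1, the median Pol2 level of the 1426 genes absent from the RNA table. The fall is therefore not shown to be a change of polymerase occupancy.

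The transcript with the largest rise in RNA was also the one with the largest Pol2 gain among genes above the median level. CG4415 gained 8.45-fold (391.6 to 3307.4), CG4842 3.65-fold and mtsh 2.61-fold. CG41056 (Pzl) gained 7.73-fold (2994.7 to 23153) and CG42621 (Myo81F), an unconventional myosin, 3.67-fold (8460 to 31059). CG40378, CG40498, CG3626, CG3348 and CG42596 gained between 2.22-fold and 2.65-fold. Beside Cyp6a17 and eggshell genes, CG13114 lost 2.77-fold, CG43965 2.69-fold, CG13822 2.66-fold, CG42565 2.5-fold and CG10163 2.42-fold.

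Of 24 chorion and vitelline membrane genes 19 lost Pol2 signal and 0 gained, all 19 adjusted over the list alone, and all 24 had a lower mean in the mutant. Cp19 lost 2.69-fold (323234 to 119977), Cp16 2.69-fold (64565 to 24005), Cp7Fa 2.79-fold and yellow-g2 2.44-fold. The median of -0.82 lay at percentile 0 of random lists, with or without length matched. No input of each genotype is listed, so lower Pol2 signal here was not set against the amount of DNA at these genes.

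Pol2 values also changed with level. With genes split by Pol2 level into 10 classes, the median log2 change was 0.60 in the lowest and -0.07 in the highest. Split by signal per kb of gene, it ran from 0.61 in the lowest class to -0.21 in the highest. At like level longer genes shifted up, with medians from -0.21 (shortest) to 0.51 (longest) in the middle of 5 level classes. In the longest of 5 length classes 43 genes were higher and 7 lower, though Spearman's rho over all genes with a length was -0.069. Lists apart on level alone were therefore read beside the match on length.

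Few members of the other lists passed in Pol2. Of 26 heterochromatin-resident genes 4 gained and 1 lost (3 adjusted over the list alone), among them CG41056, CG42621 and Scp1 (1.87-fold higher), with a median of 0.18. Muscle genes had 1 gain, bt at 1.58-fold, and 1 loss, Prm at 1.5-fold, in 29 (1 adjusted over the list alone). The neuronal gene Snap25 gained 1.77-fold, 1 of 19 in its list and 0 adjusted over the list alone. These 3 lists lay at percentile 100 and, with length matched, at 89.2, 75.7 and 93.4. Among 22 heat shock genes Hsp22 and Hsp67Bb lost 1.74-fold each, 2 in all and 0 adjusted over the list alone, at percentile 0.21 and then 10.6. Detoxification genes, 2 higher and 2 lower of 38 (1 adjusted over the list alone), included Cyp4e2 (1.72-fold lower) and GstE8 (1.79-fold higher), at percentile 38.2, and at 1.72 with changes centred on level. Tep2 of the immune list gained 1.73-fold, 1 of 46, and p53 of the DNA damage list 1.69-fold, 1 of 34, neither adjusted over the list alone, at percentiles 58.1 and 32.2.

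No piRNA pathway gene passed in Pol2, over all 38 or adjusted over the list alone, and the list lay at percentile 52.4. Authors' means were 829.4 and 805.1 for cuff, 3090.7 and 3266 for rhi, 3504.1 and 3212.9 for del, 42559 and 49617 for jing, and 16176 and 13382 for Pld. The lowest p of the piRNA list in the authors' deposited table was 0.2, for zuc (1400.2 and 848.3). Neither did any gene pass in the lists of testis (69 genes, percentile 62.1), yolk (3, percentile 97), female germline (45, percentile 1.39), follicle cells (26, percentile 97.9), fat body (15, percentile 71.4), gut (33, percentile 6.04), hemocyte (14, percentile 91.1), spermatheca (7, percentile 52.5), termination and decay (33, percentile 28.9), histone (5, percentile 32), ribosomal protein (88, percentile 52.3) and mitochondrial ribosomal protein genes (73, percentile 0). With length matched, the germline, follicle and mitochondrial ribosomal lists lay at 8.88, 65.6 and 55.6, and the ribosomal proteins at 100.

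With the deposited p adjusted again, the Pol2 changes of Hsp22, Hsp67Bb, Cyp4e2, GstE8, Tep2, p53, bt, Prm, Snap25, Scp1, CG3348, CG31646, CG43090 and Mur18B no longer passed. The preranked camera test called the eggshell, heat shock, female germline, neuron and mitochondrial ribosomal lists, as well as the testis, immune, gut, RNA decay and ribosomal protein lists that lay inside the central 95% matched on level. It did not call the follicle, muscle or heterochromatin lists, with adjusted p of 0.35, 0.1 and 0.13.

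**Figure D2:**
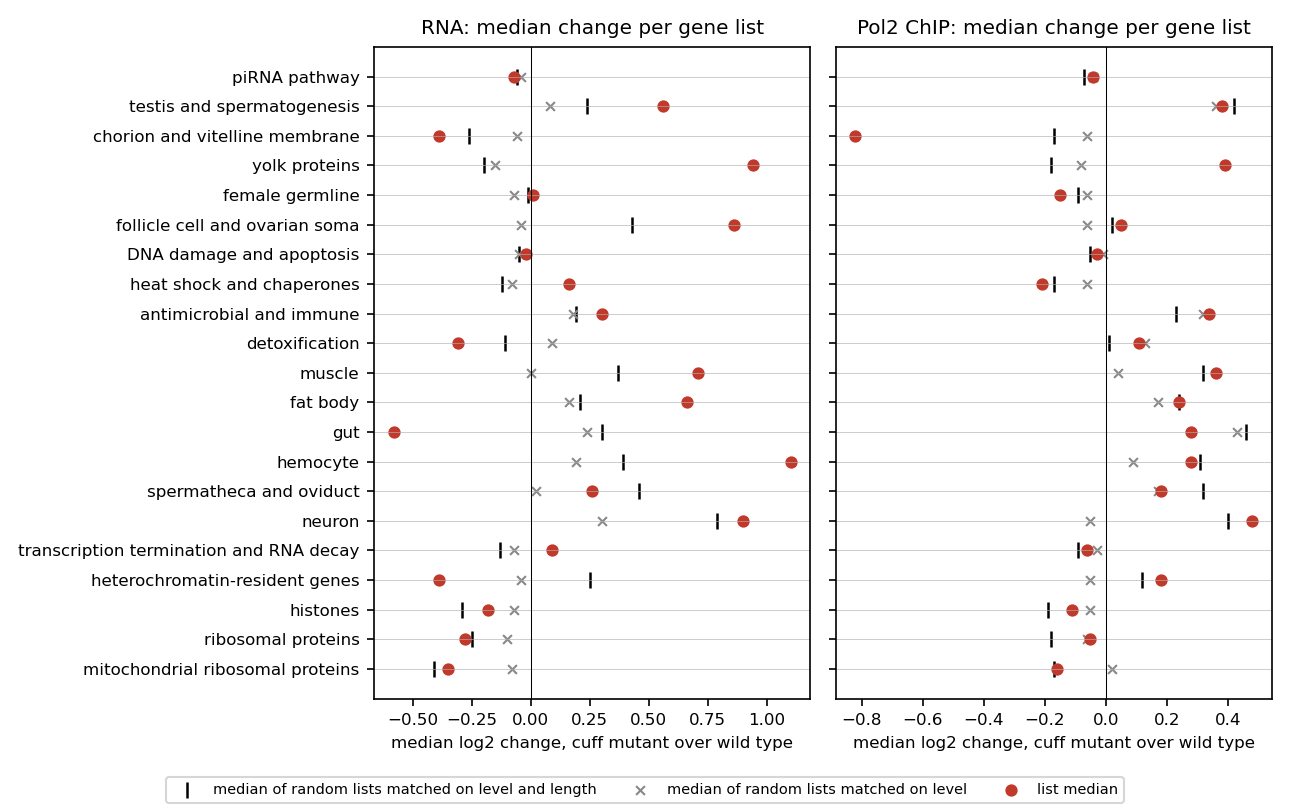
Median log2 change of each gene list (red points) in RNA and Pol2 ChIP, with the median of random lists matched on level (crosses) or on level and gene length (bars). Chorion and vitelline membrane genes lie at -0.82 in Pol2 ChIP, and the follicle cell list lies at 0.86 in RNA.

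The third question was whether RNA and Pol2 change at the same genes. Among the 12371 genes in both tables, 46 were higher in both and 29 lower in both. Independent lists of those sizes would share 5.84 and 3.14 genes, and Fisher's exact test across genes gave p = 2.9e-30 and 1e-20. The 5 with the largest RNA change were CG4415, CG42854, CG5111, CG31646 (DIP-theta) and CG43290, whose Pol2 signal rose 8.45-fold, 2.78-fold, 3.43-fold, 1.68-fold and 11.1-fold. CG31646, a cell surface protein of the immunoglobulin family, went from 2.7 to 581.1 in RNA. Across all genes Pearson's r between both log2 changes was 0.2 and Spearman's rho 0.21; among 8454 genes with a mean of 50 or more in both they were 0.33 and 0.27.

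Opposite changes were seen in 3 genes. CG43090 fell in RNA from an authors' mean of 319.1 to 0.2 while its Pol2 signal rose 2.93-fold (39.6 to 116), a log2 change of 1.53 that is 0.85 once centred on genes of like level, which also shifted up. Mur18B, a mucin-related gene, fell 2.4-fold in RNA and rose 2.66-fold in Pol2, and Prm, the muscle gene paramyosin, rose 2.42-fold in RNA and lost 1.5-fold in Pol2. The difference between both assays was not tested, since that needs values per library.

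**Figure D3:**
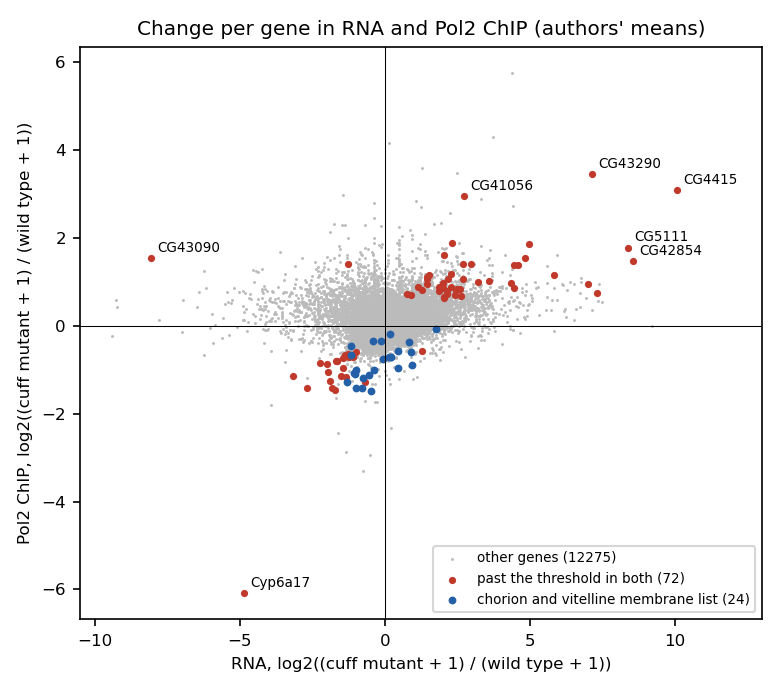
Log2 change per gene in RNA (horizontal axis) and Pol2 ChIP (vertical axis), from the authors' means plus 1, with genes past the threshold in both in red and chorion and vitelline membrane genes in blue. CG4415 lies far up in both, Cyp6a17 far down in both, and all 24 blue points lie below 0 in Pol2.

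The last measurement was ChIP of Cuff itself, with peaks in dm3 positions. The controls listed are 3 input libraries, with no ChIP from flies lacking the EGFP fusion. Peaks not due to Cuff binding could therefore not be told apart. Of 937 peaks 901 lay on the 5 main chromosome arms, 206 of them on 2R, 194 on X, 186 on 3R, 159 on 3L and 156 on 2L. Unplaced sequence held 20 (U) and 6 (Uextra), 3RHet 4, chromosome 4 held 5 and the mitochondrial genome 1. Widths ran from 206 to 6123 bp with a median of 799, and the authors' scores reached 413.6 with a median of 53.9.

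The piRNA cluster 42AB, the main germline cluster transcribed from both strands, held 32 peaks between 2.1 and 2.4 Mb of 2R. No other window of that size on 2R, in 1998 placed at steps of 10 kb, held more than 8. The peak with the highest score, 413.6, spanned 2207826 to 2211475 there, and 2 more of the 10 highest, at 2211586 to 2217240 (303.8) and 2166588 to 2169699 (263.6), also fell inside. The other 7 lay outside the 5 windows: on 3R at 772985 to 774187 (338.6) and 4756650 to 4757883 (251.5), on 2L at 21214443 to 21215464 (295.5) and 9436891 to 9437992 (239.6), and on X at 15604035 to 15604819 (275.6), 917342 to 921063 (265.7) and 20913465 to 20914516 (230.3). Clusters 38C and 80F, also transcribed from both strands, held 5 peaks each, a count reached by 76 of 2215 and 61 of 2301 other windows on their arms. Of these, 4 and 2 were in the upper part of the list by score. Cluster 20A and flamenco, transcribed from 1 strand, held 0 peaks, where other windows on X held a median of 1. Widened by 100 kb on each side, the 20A window held 2 and that of flamenco 0. With 1 list of peaks, variation between the ChIP libraries could not be assessed.

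**Figure D4:**
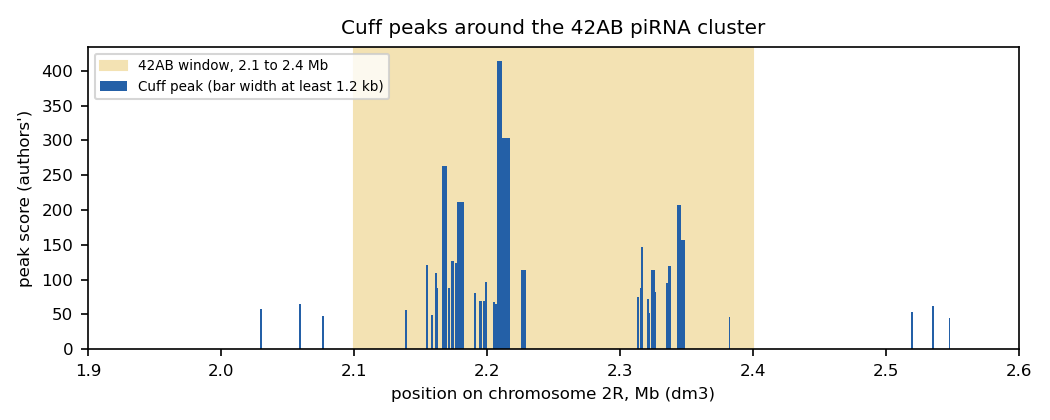
Cuff peaks on 2R (horizontal axis, Mb in dm3) with the authors' score as bar height; the shaded band is the 42AB window. The 32 peaks in the band include the highest score of the list, 413.6.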

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

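The level-matched percentile for lists replaced preranked camera after both were seen, and tests of a repeated adjustment, p strictly under 0.05, centring, gene length, a pseudocount of 10, a mean of 50 for lists and correlations, Fisher's exact test and the 2-fold overlap were also chosen after seeing the data. No paired analysis was possible because the tables hold 1 value per genotype. For the same reason DESeq2 and edgeR alternatives, other normalizations, leaving out libraries, voom, fry and an estimated correlation were not run, nor any split of the samples. Cuff-bound genes were not compared, for want of a dm3 annotation. In RNA, 1155 changed genes became 351 (241 higher, 110 lower) when the deposited p was adjusted again. In Pol2, 202 became 49 (18 higher, 31 lower) that way, and 84 (56 higher, 28 lower) with at least a 2-fold difference. The 75 genes changed the same way in both assays became 24 and 34 under these settings, and the 3 opposite genes became 0 with p adjusted again. Of 20 lists, 10 were apart in RNA, against 6 with gene length matched (4 by both matches), 4 by Fisher's exact test, 5 by camera and 3 by camera on centred changes. In Pol2 8 were apart, against 2 with gene length matched (1 by both), 3 by Fisher's exact test, 10 by camera and 7 by camera on centred changes. A pseudocount moves no gene's call, which rests on the deposited p, but moved 3 RNA lists. Of 179 named gene results 35 no longer passed when p was adjusted again, and 0 of those past the threshold changed direction with centring. A pseudocount added to both genotypes cannot change a gene's direction, so it was no test of that. Peaks in the 5 windows numbered 42, and 34 to 49 with other score, overlap and window settings. Apart from the repeated adjustment, which can only remove calls, the cause of these moves was not tested. Low values limit the gut, neuron and testis lists in RNA, where 2 of 26, 7 of 19 and 15 of 40 members had a wild-type mean of 50 or more. Depth per library is unknown.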

Other observations

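The genes in this paragraph were chosen after their values were seen. RNA of the mitochondrial genome was lower in the mutant: 12 of 13 genes fell, from 2.26-fold for mt:ND1 to 3.85-fold for mt:ND4L, and mt:ND2 had authors' means of 7462.7 and 3742.7. Of 65 nuclear genes of the respiratory chain 4 fell and 1 rose, with a median log2 change of -0.32 at percentile 0.01 of random lists matched on level, and 34 with length matched. Picked for their large rises, outside the fixed lists and with no count of similar genes that did not rise, were Rcd-1r (19.9 to 995.6), TfIIA-S-2 (50.7 to 923.1), betaNACtes3 (1.3 to 167.4) and the neighbours skpC (57.6 to 2105.2), skpD (1.1 to 145.7) and skpE (5.6 to 166.3). In Pol2 none of these 6 passed; Rcd-1r had means of 188.8 and 483.3. Near Cyp6a17, its close relative Cyp6a23 had Pol2 means of 1968.4 and 2140.3 and RNA means of 858 and 879.9, while Cyp6a22 fell 4.75-fold in RNA and 1.79-fold in Pol2.

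Genes next to the centromere, a group chosen after seeing the data, fell more often than they rose in RNA on 4 of 5 arms. Of the 60 genes nearest the centromere in gene order, 19 fell and 4 rose on 2L, 12 fell and 4 rose on 2R, and 15 fell and 1 rose on 3L. Their medians of -0.45, -0.60 and -0.39 lay at percentile 0 of lists matched on level and length. Those on X, 3 lower and 1 higher, had a median of -0.10 at percentile 1.89, and those on 3R, 4 lower and 5 higher, one of 0.19 at 94.6. For Pol2 the 60 genes per arm were picked anew, and both picks took only genes above a low mean value. The RNA and Pol2 sets can therefore differ. On 2R 6 genes were higher and 0 lower in Pol2, at percentile 97.9. Of these 6, CG40498, l(2)41Ab and CG42596 also rose in RNA. The Pol2 sets on 2L, 3L and 3R lay at 17.4, 69.4 and 62.8, and on X at 1.49. Histone copies, which can share reads, make up 18 of the 2L genes and 8 of the falls there; without them 11 of 42 fell and 4 rose, with a median of -0.40 at percentile 0. Genes called at 2-fold also lay side by side: 30 adjacent pairs fell in RNA, against at most 19 in 2000 permutations within length classes, and 51 pairs rose, against at most 39. In Pol2 7 adjacent pairs fell, against at most 2, and 3 rose, against at most 3. The permutations did not keep the level of genes or merge neighbours that share reads. The excess alone therefore does not show that neighbours change together. Runs in RNA included CG17715, lt and CG40005 on 2L, which fell, and CG32793, CG3592, CG3598, CG14420 and CG14421 on X, which rose. Another, CG43965, Cp18 and Cp15 on 3L, fell. Each Pol2 run that fell held eggshell list members: Cp15, Cp19 and Cp16, then yellow-g and yellow-g2 beside CG32302, then Femcoat beside CG15570 and CG15571.

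For the patterns below, tests of attached tissue, egg chamber stage, background over gene bodies, the length trend within each list and length-matched Pol2 percentiles were chosen after the result was seen, and the length trend took the place of tests first written for Cyp6a17. Pol2 signal of weakly occupied genes was higher in the mutant. More transcription of those genes stays open. Genes in the RNA table did not show the predicted upward shift relative to 1426 genes not in it at the same Pol2 level. The difference was -0.04 (95% bootstrap interval over genes -0.0679 to -0.0141). Genes in the RNA table at that level can have almost no RNA, so this cannot decide the question. Split by RNA level, median RNA changes were -0.193, 0.828, 0.622 and 0.336 in classes 1 to 4 of 10. Those 1426 genes rose by a median log2 of 0.55 (0.529 to 0.58), while the most occupied of 10 classes lay at -0.07. Lower enrichment over background in the mutant ChIP is a candidate explanation, and whether it came from the chromatin or the libraries was not tested.

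RNA of long genes was higher and of short genes lower in the mutant. In Pol2 longer genes also shifted up at like level, as given above. Even background over gene bodies is argued against, since among the most abundant of 5 classes of genes the longest and shortest classes still differed by 0.68 (0.568 to 0.796), and among the class with the highest signal per kb by 0.59 (0.462 to 0.702). More RNA of somatic cells is argued against as the whole source, since rho between length and change was 0.60 (0.448 to 0.721) over 111 germline, piRNA pathway and RNA decay genes, a test written with the trend over all genes already known. A length bias of the libraries or the counting that acts on every gene could give this value but stays open, since rho was 0.066 in ribosomal protein, 0.073 in heat shock, -0.055 in detoxification and -0.13 in testis genes. A change in unspliced RNA in the mutant stays open, untested.

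Muscle and follicle RNA medians were high, and chorion RNA and eggshell Pol2 signal low: chorion genes had medians of -0.78 in RNA and -1.07 in Pol2, vitelline membrane genes 0.20 (0 of 7 lower) and -0.60 (6 of 7 lower). A larger share of every attached tissue stays open: the gut list at percentile 0.675, Mal-A1 (329.6 to 1.6) and Send1 of the spermatheca (798.9 to 0.3) go against it, but only 2 of 26 gut genes had a wild-type mean of 50 or more, and the spermatheca list, where Send1 alone fell, lay at 70.9. Fewer late egg chambers may lower chorion genes more than the earlier vitelline membrane genes; the difference of medians was -0.97 in RNA (-1.95 to 0.019) and -0.47 in Pol2 (-0.854 to -0.109), and the RNA interval keeps it open. A change of the same size in polymerase occupancy of these genes stays open: the lower of the muscle and follicle Pol2 percentiles was 97.9 matched on level, which met the test first written, and 65.6 with length matched. Their Pol2 medians were 0.36 and 0.05, against 0.71 and 0.86 in RNA, where length-matched random lists already lay at 0.37 and 0.43.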
